A study of Danio rerio with 11 samples.

How the data were processed

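RNA from the brains of adult male zebrafish was measured on 11 one-colour Agilent zebrafish arrays of the 4 × 44K design. Per the labels, groups of 20 male fish were kept in 20 L tanks for 14 days with 273 ng/L diazepam, 273 µg/L diazepam or no diazepam, and 600 ng of total RNA per sample was labelled with Cy3. The labels state 4 replicates per group, and 3 control, 4 low-dose and 4 high-dose arrays were analysed. How many brains went into each RNA sample is not given in the sources used here. The groups were taken from the labels of each sample.

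Per the file headers, the scanner files were made with Agilent Feature Extraction 9.5.3.1 and hold a processed signal, an intensity that was background-subtracted and corrected for trends across the array, with small values replaced by surrogates. The files also hold the mean spot intensity and the local background intensity per the file headers, and marks for spots well above background, saturated spots and outlier spots. No scaling between arrays was found. The deposited value table holds intensity as well, and all 45220 features of every array had the same value there as in the scanner file, so it was used only as an alternative. Its column medians were 134.4, 91.6 and 132.5 for control replicates 1 to 3, 123.4, 145.9, 124.2 and 101.3 for low-dose replicates 1 to 4, and 162.4, 128.0, 95.8 and 79.5 for high-dose replicates 1 to 4. Probe positions were taken from the same files, where they refer to the Zv7 build, and no genome of that build was used here.

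Of 43803 spots that are not controls, spots of the same probe name were averaged, which left 43603 probes, and 41776 of them had a position. Probes were matched to a RefSeq gene table by RefSeq accession, and failing that by gene number, symbol or synonym. Of 19212 probes with their own RefSeq accession, 15163 matched, and 21096 probes had 1 gene (14335 genes). Spots marked as outliers by the scanner software, 198 in all or 0.0411% of spots, were set to missing. That step was added after the other choices were fixed, and an alternative keeps these spots.

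The log2 of the processed signal was taken and the 75th percentile of each array over probes that are not controls was subtracted. A probe was kept if it was well above background on every array of at least 1 group, which left 30857 probes, 18184 of them with 1 gene (12590 genes), and 4411 genes had several kept probes. Only 1 probe had a saturated spot. A single linear model with the 3 groups was fitted to the 11 arrays (8 residual degrees of freedom) with limma 3.58.1 in R 4.3.3, and the 3 comparisons were taken from it as two-sided moderated tests. A probe was called at a Benjamini-Hochberg adjusted p under 0.05 over all kept probes. A lenient count used an unadjusted p under 0.01 and a change of at least 1.5-fold. Tables were read with pandas 2.3.3 and the plots were drawn with matplotlib 3.10.9. Where a probe was well above background on no array of a group, the change is given as a bound, "at least N-fold", computed against a floor, the lowest signal that was well above background on each array of that group (or the probe's own signal where that was higher). Fisher's exact test was one-sided, for more called genes in a list than elsewhere.

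Gene lists were tested with limma's camera on 1 probe per gene, the kept probe of the highest mean signal, with the preset correlation of 0.01 between genes, and with Benjamini-Hochberg adjustment over the lists of a comparison. Lists needed at least 5 measured genes, and 27 were tested. They cover GABA-A receptor subunits, GABA synthesis and transport, glutamate receptors and transporters, the monoamine system, neuropeptides, the circadian clock and its output, immediate early genes, the corticotropic stress axis, neurosteroid synthesis, xenobiotic metabolism and efflux, heat shock and oxidative stress, p53 and DNA damage, the respiratory chain, cytosolic ribosomal proteins, the proteasome and the cell cycle. Markers of cell types and tissues cover synaptic and neuronal genes, astroglia, oligodendrocytes, microglia and leukocytes, erythrocytes, vessels and meninges, pituitary, retina and pineal, lens, skeletal muscle, and cartilage, bone and skin. The lists, groups, tests, filter, alternatives and rule for named genes were fixed before the data were examined. A list of sterol synthesis genes and Fisher's exact test on the lists were added after seeing the data.

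The genes named in the text follow a rule. For each comparison with the control these are the 10 genes with the largest increase and the 10 with the largest decrease among called probes that carry 1 gene. If fewer pass in a direction, places are filled up to 5 with genes of the smallest unadjusted p, given as values that did not pass. Between the doses 5 and 5 genes were taken, with 3 for filling. For each list, up to 4 members of the smallest unadjusted p could be named, and gad1b, gad2, tspo and per1b were given where measured. Some results that the rule asks for are not reported here. A gene is given by its brightest kept probe unless it was named for another probe. Symbols that are only identifiers were passed over. Genes outside the rule are said to have been chosen after their values were seen.

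The file headers give 3 slides, of which slide 1 holds control replicates 1 and 2, low-dose replicate 1 and high-dose replicate 1, slide 2 holds control replicate 3, low-dose replicates 2 and 3 and high-dose replicate 2, and slide 3 holds low-dose replicate 4 and high-dose replicates 3 and 4. All slides were scanned on 1 date. Slide 3 has no control array. Replicate numbers in the labels run across the groups, so pairing was checked by correlating, over 30800 probes, the deviations from the group means of arrays with the same number. The correlations were 0.467, 0.318 and 0.735 between control and low dose, 0.162, 0.260, 0.243 and 0.489 between low and high dose, and 0.0347, 0.311 and 0.201 between control and high dose. With a threshold of 0.1 in every pair, only control with low dose and low dose with high dose were treated as paired. Their values with replicate as a block are given beside the results where they change a call or move a count by over 1.5 times. The check cannot show pairing, since arrays with different numbers were not correlated for comparison and deviations within a group depend on each other. Arrays of the same number also often share a slide, as all those of replicate 1 do, so a correlation may reflect the slide. Control replicate 3 and low-dose replicate 3 also share high skeletal muscle markers.

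The fit was tested on simulated data with known changes added to 50 of 30800 probes at each size. Of changes of 0.5, 1, 1.5 and 2 (log2), 18%, 66%, 86% and 92% were called for the low dose, 12%, 74%, 82% and 88% for the high dose and 20%, 68%, 98% and 96% between the doses, with 7, 8 and 6 false calls. In simulated groups without change 0 of 81 camera tests were called. Those groups were drawn without correlation between genes, so this count says nothing about false calls of camera where genes are correlated. The correlation of the dose effects was set against 1000 simulated draws that share the control arrays.

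The alternatives planned were normexp background correction with an offset of 50, quantile normalization, median centring, the deposited value table, no filter on dim probes, a stricter filter, a fit of only the 2 groups compared, replicate as a block, slide as a block, array weights, limma's eBayes with trend and robust settings, an estimated correlation in camera, the mean of all kept probes per gene, and leaving out each array. Alternatives chosen after seeing the data were keeping spots marked as outliers, leaving out control replicate 3 and low-dose replicate 3 together, the mean of the skeletal muscle markers as a covariate, and normexp after local backgrounds over 100 were replaced by the median background of the array. An estimated correlation in camera together with a block, or with control replicate 3 left out, was added after seeing the data too.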

Results

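Gene expression was measured in the brains of adult male zebrafish that had been kept for 14 days in water without diazepam, in water with 273 ng/L diazepam (the low dose) or in water with 273 µg/L diazepam (the high dose). Diazepam is a benzodiazepine, a drug that strengthens the response of GABA-A receptors to the inhibitory transmitter GABA. Per the labels, the low dose stood for a worst case in the environment and the high dose for a level without an observed effect in a test on early life stages. There were 3 water control arrays, 4 low-dose arrays and 4 high-dose arrays, 11 in all, each a one-colour Agilent array of the 4 × 44K zebrafish design. Each array is named here by its group and replicate number. The 75th percentile of the processed signal ran from 849 on high-dose replicate 4 to 1663 on high-dose replicate 1. The share of spots well above background was 71.3%, 73.4% and 76.6% on control replicates 1 to 3, and 73.1%, 70.4%, 77.1% and 75.5% on low-dose replicates 1 to 4. It was 69.6%, 69.7%, 61.2% and 72.9% on high-dose replicates 1 to 4. The number of arrays limits the precision. The labels do not say that the RNA of each array came from separate animals, so the p-values measure only spread between these samples, which may be technical.

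The first comparison asks what the low dose changed against the water control. Circadian clock genes had the largest changes in both directions. The clock repressor ciarta fell by 3.19 ± 0.11 (SE, log2 scale, n = 4 and 3) with an adjusted p of 7.3e-07. The nuclear receptor nr1d1, which represses bmal genes, fell by 2.66 ± 0.08 (adjusted p = 3.19e-07). The period gene per1b fell by 1.94 ± 0.11 (adjusted p = 4.51e-05) and per3 fell by 1.73 ± 0.13 (adjusted p = 1.50e-04). In the other direction, the bZIP repressor genes nfil3-5 and nfil3-2 rose by 2.55 ± 0.13 (adjusted p = 2.42e-05) and 2.53 ± 0.14 (adjusted p = 3.04e-05), and the clock activator bmal2 rose by 1.35 ± 0.09 (adjusted p = 6.59e-05).

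On the Zv7 genome build, per the file headers, the probe of ciarta (NCBI gene 564009) lies on chromosome 19 from 6603456 to 6603515, and that of nr1d1 (gene 494487) on chromosome 3 from 22779928 to 22779987. The probe of nfil3-5 (gene 335737) lies on chromosome 6 from 6406806 to 6406865, that of per1b (gene 406204) on chromosome 7 from 51066470 to 51066529, and that of per3 (gene 58107) on chromosome 11 from 39535566 to 39535625. The normalized log2 signal of ciarta, which is relative to the 75th percentile of the array, was 2.19 ± 0.15 (SD, n = 3) in the control and -1.0 ± 0.13 (SD, n = 4) at the low dose. That of nfil3-5 was 1.39 ± 0.22 in the control and 3.94 ± 0.09 at the low dose. A second probe of nr1d1 gave a change of -2.58.

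Of the other genes with the largest decreases, per1a changed by -2.54 ± 0.20, although its brighter probe changed by -0.69 and did not pass. The photolyase-like genes cry5 and cry-dash changed by -1.84 ± 0.13 and -1.69 ± 0.14, ddb2, whose product recognizes damaged DNA in nucleotide excision repair, by -1.55 ± 0.13, and the heat shock factor hsf2 by -1.43 ± 0.13. The zinc finger gene znf395b changed by -1.65 ± 0.12, with low-dose replicate 1 apart from the other low-dose arrays. Adjusted p-values of these 6 genes ran from 1.46e-04 to 8.82e-04. Of the other genes with the largest increases, the opsin opn3 changed by 1.18 ± 0.09, the clock activator bmal1a by 1.11 ± 0.09, nfil3 by 1.06 ± 0.10, mxd3 by 1.00 ± 0.12, impdh1b, an enzyme of guanine nucleotide synthesis, by 0.93 ± 0.11, cry3b by 0.73 ± 0.11 and the cytokine gene il17a/f2 by 0.66 ± 0.10. Their adjusted p-values ran from 1.50e-04 to 0.0333. A second probe of cry3b gave 0.73 and did not pass, and the other probes of impdh1b gave 0.82 to 1.09, with 2 of them past the threshold. Outside these, the steroid dehydrogenase hsd17b3 (-0.67 ± 0.11, adjusted p = 0.0459) and the sulfotransferase sult2st1 (-0.65 ± 0.10, adjusted p = 0.0333) passed as members of gene lists. For all 22 called genes that the rule named here, the low-dose and control arrays did not overlap, which chance gives for 5.71% of genes not chosen by a test. These genes were chosen by the test, so this adds no separate evidence.

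In all, 87 of 30857 probes passed limma's test at an adjusted p of 0.05, with 28 higher and 59 lower, and 61 of them belong to a single gene (51 genes). Of the 87, 43 changed by at least 2-fold. Outside the clock list lie 61 of the 87, a count that includes the 26 probes matched to no single gene. At an unadjusted p under 0.05 there were 2157 probes. In each comparison, chance gives such a p for a share of 0.05 of the probes or list members tested. The lenient count, an unadjusted p under 0.01 with a change of at least 1.5-fold, was 206 (75 higher, 131 lower), while chance gives 308.6 probes at that p alone, before the size limit. Within slides 1 and 2, the slides that hold both groups, 87 of 87 probes kept their direction. They were called on these same arrays, so this is no separate evidence against a slide effect. With slide as a block 72 probes passed, and hsd17b3 (adjusted p = 0.0614), il17a/f2 (0.0574), sult2st1 (0.0752) and cry3b (0.0646) did not. With replicate as a block 108 passed, but hsd17b3 (0.112), il17a/f2 (0.0532) and sult2st1 (0.0623) did not, and the lenient count was 340. Leaving out control replicate 1, 2 or 3 gave 54, 56 or 53 probes, and leaving out both control replicate 3 and low-dose replicate 3, whose skeletal muscle markers were high, gave 38, of which 36 are among the 87.

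Among the gene lists, 18 of 40 measured clock genes passed over all probes at the low dose (7 up, 11 down), and 30 adjusted over the list alone (13 up, 17 down). The test of limma's camera, which looks for a shift in 1 direction, did not call the clock list (adjusted p = 0.106). Camera called 7 of 27 lists at the preset correlation and 0 with an estimated correlation, where the lowest adjusted p was 0.186 and 3 lists had an unadjusted p under 0.05. Immediate early genes, which neurons switch on within minutes of activity, were higher as a group (median log2 change 0.16, adjusted p = 1.02e-07). That call was lost, with an adjusted p = 0.272 with an estimated correlation. Over all probes 0 of 36 members passed limma's test (7 at an unadjusted p under 0.05), and 3 rose when adjusted over the list alone. The phosphatase gene dusp2 stood at 0.84 and egr2a at 0.86, neither of which passed over all probes (adjusted p = 0.107 and 0.308).

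Markers of astroglia and radial glia were lower as a group (median -0.16 over 23 genes, adjusted p = 5.12e-04; adjusted p = 0.186 with an estimated correlation). In that list glulb, which encodes glutamine synthetase, stood at -0.43 and the glutamate transporter gene slc1a3a at -0.38, neither of which passed (adjusted p = 0.409 and 0.418). Markers of microglia and leukocytes were lower (median -0.18 over 33 genes, adjusted p = 5.12e-04; adjusted p = 0.803 with an estimated correlation), and without low-dose replicate 1 that call was lost (adjusted p = 0.0502). The apolipoprotein gene apoeb stood at -0.35 and did not pass (adjusted p = 0.520). Vascular and meningeal markers were lower (median -0.20 over 32 genes, adjusted p = 0.00664; adjusted p = 0.803 with an estimated correlation), a call lost without control replicate 3 (adjusted p = 0.103), low-dose replicate 1 (0.0778) or low-dose replicate 4 (0.168). Erythrocyte markers were higher (median 0.39 over 22 genes, adjusted p = 6.57e-04; adjusted p = 0.803 with an estimated correlation), a call lost without low-dose replicate 3 (adjusted p = 0.0586). Its members hemgn and hbae1.1 stood at 0.78 and 0.74 and did not pass (adjusted p = 0.423 and 0.546). In these 4 marker lists 0 genes passed limma's test over all probes and 0 adjusted over the list alone, while 5 astroglial, 5 microglial, 3 vascular and 5 erythrocyte markers had an unadjusted p under 0.05.

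Respiratory chain genes were lower as a group (median -0.06 over 85 genes, adjusted p = 0.00279; adjusted p = 0.803 with an estimated correlation). Over all probes 0 of them passed limma's test (5 at an unadjusted p under 0.05) and 1 fell when adjusted over the list alone, while the assembly factor gene ndufaf4 stood at -0.40 (adjusted p = 0.101), with low-dose replicate 1 apart from the others. Genes of xenobiotic metabolism and efflux were lower (median -0.09 over 51 genes, adjusted p = 0.00664; adjusted p = 0.186 with an estimated correlation). Of these 1 fell, sult2st1, and the list's call was lost without control replicate 1 (adjusted p = 0.0650). Within slides 1 and 2 the medians of these lists were 0.30 and 0.23 for immediate early genes, -0.13 and -0.20 for astroglia, -0.31 and -0.10 for microglia, -0.26 and -0.08 for vascular markers, 0.03 and 0.53 for erythrocytes, -0.08 and -0.08 for the respiratory chain, and -0.16 and -0.07 for xenobiotic metabolism. With slide as a block all 7 were called at the preset correlation, with adjusted p-values of 5.73e-07, 0.00209, 2.63e-04, 0.00494, 0.0145, 3.96e-06 and 0.0261 in the same order. These calls were lost too, with adjusted p = 0.535, 0.2105, 0.687, 0.687, 0.717, 0.535 and 0.535 with an estimated correlation and the block.

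**Figure D1:**
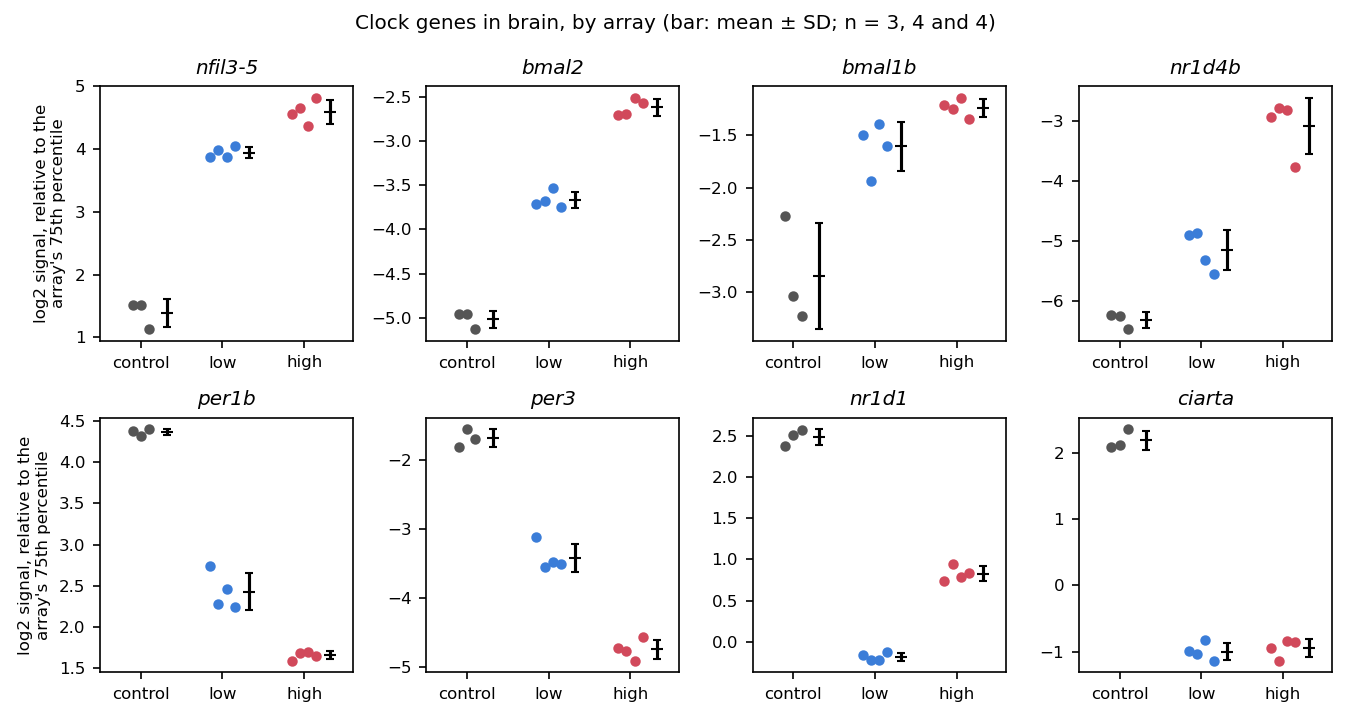
Normalized signal of 8 clock genes on each array (vertical axis, log2 signal relative to the 75th percentile of the array) in the water control (n = 3), low-dose (n = 4) and high-dose (n = 4) groups, where points are arrays and bars show the mean ± SD. The control and high-dose arrays do not overlap for any of the 8 genes, all of which passed the test on these arrays. The gene ciarta changed by -3.19 at the low dose and -3.13 at the high dose.

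The second comparison asks what the high dose changed against the water control. The clock genes again had the largest changes. The gene ciarta fell by 3.13 ± 0.11 (SE, log2 scale, n = 4 and 3, adjusted p = 1.26e-06), per3 fell by 3.06 ± 0.13 (adjusted p = 1.37e-06) and per1b fell by 2.72 ± 0.11 (adjusted p = 1.56e-06). The genes nfil3-2 and nfil3-5 rose by 3.45 ± 0.14 and 3.21 ± 0.13 (adjusted p = 1.37e-06 for both), and bmal2 rose by 2.39 ± 0.09 (adjusted p = 1.26e-06). Outside the clock, gabrr1, which encodes a rho subunit of GABA-A receptors, fell by 2.10 ± 0.22 (adjusted p = 8.54e-04), and the heat shock gene hsp70l fell by 1.76 ± 0.13 (adjusted p = 9.74e-05).

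The nuclear receptor gene nr1d4b, of the same family as nr1d1, was at least 9.49-fold higher at the high dose (adjusted p = 1.08e-04). It is given as a bound since 0 of 3 control arrays gave a signal well above background. The probe's own control signal was above the floor, so the bound equals the plain estimate (log2 change 3.25) and is not a cautious one. For nr1d4b high-dose replicate 4 stood apart from the other high-dose arrays. The cone arrestin gene arr3b was at least 2.70-fold lower (adjusted p = 0.00163), with 0 of 4 high-dose arrays well above background, although under the planned normexp correction it stood at 0.45. The probe of nr1d4b (gene 571948) lies on chromosome 11 from 1373341 to 1373400, and that of gabrr1 (gene 568984) on chromosome 20 from 904296 to 904355. The other genes with the largest decreases were cry5 (-2.12 ± 0.13), ddb2 (-1.98 ± 0.13), cry-dash (-1.97 ± 0.14) and the clock repressor bhlhe41 (-1.82 ± 0.14), with adjusted p-values from 2.33e-05 to 1.09e-04, and per1a, whose brighter probe changed by -0.79 ± 0.15 (adjusted p = 0.0243) and whose other probe changed by -2.25. The other genes with the largest increases were nr1d4a (2.10 ± 0.15), ndrg1b (1.96 ± 0.20), opn3 (1.70 ± 0.09), ugt5g1 (1.64 ± 0.21), bmal1b (1.61 ± 0.21) and cry3b (1.56 ± 0.11), with adjusted p-values from 4.92e-06 to 0.00371. Product names place ugt5g1 among the glucuronosyltransferases. For nr1d4a, high-dose replicate 2 stood apart from the others. The clock genes nr1d1 (-1.65, adjusted p = 4.02e-06) and bhlhe40 (-1.66, adjusted p = 1.09e-04) were chosen after their values were seen, and for bhlhe40 high-dose replicate 3 stood apart. For all 44 called genes that the rule named here, the high-dose and control arrays did not overlap. Chance gives that for 5.71% of genes not chosen by a test, but these were, so it adds no separate evidence.

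Of the 40 measured clock genes, 13 rose and 14 fell over all probes, and 14 rose and 18 fell when adjusted over the list alone. Camera did not call the list in 1 direction (adjusted p = 0.645). The 27 clock genes called at the high dose include all 18 called at the low dose, and 27 of 27 had the same sign at both, in comparisons that share their control arrays. Of the 18 called at the low dose, 15 changed further at the high dose. Only the comparison of the doses themselves tests single genes for such a difference.

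Camera called 6 of the 27 lists at the preset correlation and 0 with an estimated correlation, where the lowest adjusted p was 0.109 and 3 lists had an unadjusted p under 0.05. Genes of the mitochondrial respiratory chain were lower as a group (median log2 change -0.17 over 85 genes, adjusted p = 4.61e-11; adjusted p = 0.382 with an estimated correlation). Of these 5 fell over all probes and 22 fell when adjusted over the list alone. They include the assembly factor genes ndufaf4 (-0.54 ± 0.08, adjusted p = 0.00654), sdhaf2 (-0.55 ± 0.10, 0.0244) and sdhaf3 (-0.42 ± 0.08, 0.0244), and sdhb, a subunit of complex II (-0.32 ± 0.07, 0.0406). Neuropeptide genes were lower as a group (median -0.31 over 30 genes, adjusted p = 1.25e-05; adjusted p = 0.532 with an estimated correlation). Of these 4 fell over all probes, npvf (-0.78 ± 0.13, adjusted p = 0.0129), nmba (-0.77 ± 0.14, 0.0215), the appetite peptide gene cart2 (-0.64 ± 0.13, 0.0380) and uts1 (-0.42 ± 0.08, 0.0329), while 1 rose and 6 fell when adjusted over the list alone.

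Genes of xenobiotic metabolism and efflux were lower as a group (median -0.16 over 51 genes, adjusted p = 5.51e-04; adjusted p = 0.109 with an estimated correlation). Of these 5 fell over all probes, and 1 rose and 13 fell when adjusted over the list alone. The cytochrome P450 gene cyp2ad6 changed by -1.40 ± 0.17 (adjusted p = 0.00247), sult2st1 by -0.88 ± 0.10 (0.00175), the efflux transporter gene abcc4 by -0.74 ± 0.13 (0.0219) and nr1i2, the pregnane X receptor, by -0.73 ± 0.13 (0.0171), although under the planned normexp correction nr1i2 stood at 0.25. For abcc4, high-dose replicate 1 stood apart from the others. Heat shock and oxidative stress genes were lower as a group (median -0.07 over 48 genes, adjusted p = 0.00128; adjusted p = 0.382 with an estimated correlation). Of 49 measured, 1 of them without a value on every array, 7 fell over all probes, and 3 rose and 16 fell when adjusted over the list alone. Besides hsp70l they include hsf2 (-1.61 ± 0.13, adjusted p = 1.89e-04) and the mitochondrial chaperone genes hspe1 (-0.69 ± 0.10, 0.00588) and hspd1 (-0.43 ± 0.08, 0.0286).

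Markers of astroglia and radial glia were lower as a group (median -0.20, adjusted p = 0.00128; adjusted p = 0.191 with an estimated correlation), with 0 passing limma's test over all probes (7 at an unadjusted p under 0.05) and 6 lower when adjusted over the list alone. In that list glulb stood at -0.42 and slc1a3a at -0.45, neither of which passed (adjusted p = 0.154 and 0.0873). Cell cycle genes were higher as a group (median 0.14 over 36 genes, adjusted p = 0.00601; adjusted p = 0.879 with an estimated correlation), with 0 passing limma's test over all probes and 0 adjusted over the list alone (9 at an unadjusted p under 0.05), and the call was lost without high-dose replicate 1 (adjusted p = 0.178). The replication helicase gene mcm7 stood at 0.48 and the cyclin gene ccnb2 at 0.28, neither of which passed (adjusted p = 0.127 and 0.220).

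Several lists that camera did not call held called members at the high dose. The p53 and DNA damage list (adjusted p = 0.563) had 1 gene up and 3 down, and 4 up and 4 down adjusted over the list alone. In it the glycosylase gene neil1 changed by -0.82 ± 0.12 (adjusted p = 0.00686) and the pro-apoptotic gene bbc3 by 0.52 ± 0.07 (0.00502). Its 3 lower genes include cry5, which is in the clock list too. The corticotropic list (adjusted p = 0.842) had 3 genes down, and 2 up and 4 down adjusted over the list alone. Among the 3 are per1a, which is in the clock list too, and crhbp (-0.81 ± 0.14, 0.0171). The latter encodes a binding protein of corticotropin-releasing hormone. The neurosteroid list (adjusted p = 0.246) had 2 genes down by either count, hsd17b3 (-1.20 ± 0.11, 3.49e-04) and hsd17b10 (-0.36 ± 0.07, 0.0380). The immediate early gene list (adjusted p = 0.242) had 1 gene up, dusp2 (1.11 ± 0.17, 0.00818), and 3 up adjusted over the list alone. The proteasome list (adjusted p = 0.331) had 1 gene up by either count, psmd5 (0.42 ± 0.08, 0.0242). The cartilage, bone and skin list (adjusted p = 0.242) had 1 gene down by either count, the keratin gene krt18a.1 (-0.65 ± 0.13, 0.0302).

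In all, 553 of 30857 probes passed limma's test, 197 higher and 356 lower, and 378 of them belong to a single gene (310 genes). Of the 553, 147 changed by at least 2-fold. Outside the clock list lie 515 of the 553, a count that includes the 175 probes matched to no single gene. At an unadjusted p under 0.05 there were 4488 probes, and the lenient count was 729 (186 higher, 543 lower) against 308.6 by chance at that p alone. Within slides 1 and 2, 553 of 553 probes kept their direction, which adds no separate evidence, since they were called on these same arrays. With slide as a block 402 passed. Named genes that did not pass with that block were hsd17b10 (adjusted p = 0.0542), per1a (0.0548), nr1i2 (0.0582), sdhaf2 (0.0731), cart2 (0.0793), sdhb (0.0833), abcc4 (0.0852), crhbp (0.0864), uts1 (0.0975) and krt18a.1 (0.111). Leaving out control replicate 1, 2 or 3 gave 248, 257 or 242 probes, and leaving out high-dose replicate 4 gave 362. Without control replicate 3 and low-dose replicate 3 together there were 227, of which 212 are among the 553.

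Within slides 1 and 2 the list medians at the high dose were -0.29 and -0.21 for the respiratory chain, -0.48 and -0.20 for neuropeptides, -0.16 and -0.21 for xenobiotic metabolism, -0.25 and -0.15 for astroglia, -0.11 and -0.12 for heat shock genes, and 0.34 and 0.12 for cell cycle genes. With slide as a block all 6 were called at the preset correlation, with adjusted p-values of 1.96e-19, 3.35e-04, 0.00124, 3.99e-04, 2.66e-04 and 1.90e-04 in the same order. These calls were lost too, with adjusted p = 0.113, 0.676, 0.166, 0.113, 0.3545 and 0.676 with an estimated correlation and the block. That block also called immediate early genes and the neurosteroid list (adjusted p = 0.0281 for both), calls that were lost, with adjusted p = 0.676 and 0.444 with an estimated correlation.

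**Figure D2:**
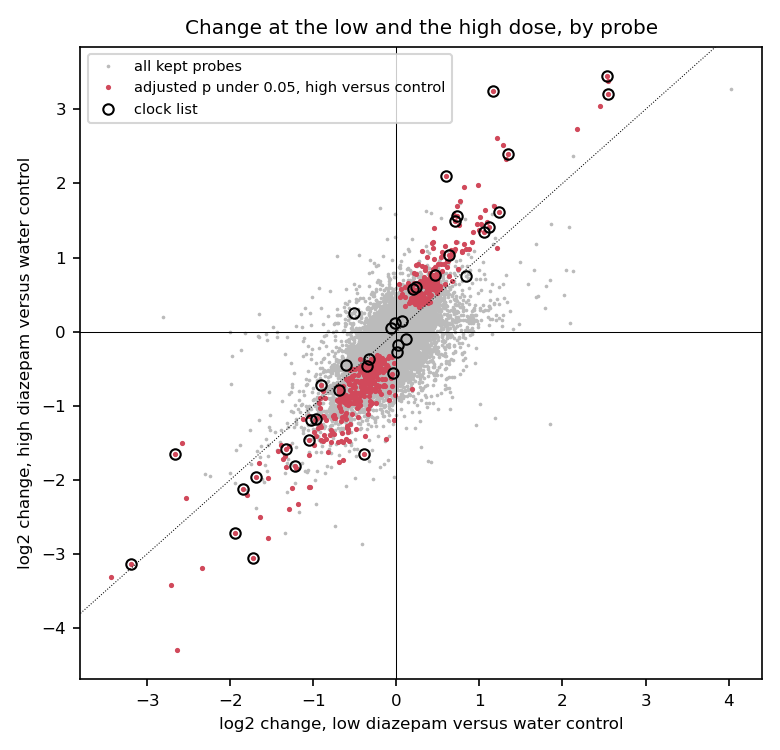
Change of each kept probe at the low dose (horizontal axis, log2 against the water control) and at the high dose (vertical axis, same unit), where red points passed at the high dose, circles mark genes of the clock list and the dotted line marks equal change. Of the 18 clock genes called at the low dose, 15 lie further from 0 at the high dose.

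GABA-A receptor subunits, the targets of diazepam, were not called as a list (8 measured, adjusted p = 0.125 at the low dose, 0.331 at the high dose and 0.894 between the doses). Over all probes 0 subunits passed limma's test at the low dose (2 at an unadjusted p under 0.05), where gabrr1 stood at -1.04 (adjusted p = 0.150) and 1 was lower adjusted over the list alone, and at the high dose gabrr1 alone fell by either count. The list of GABA synthesis, transport and receptor partners was not called (adjusted p = 0.910, 0.407 and 0.265 in the same order). The GABA synthesis genes gad1b and gad2 stood at -0.29 ± 0.10 and 0.01 ± 0.09 at the low dose and at -0.36 ± 0.10 and -0.18 ± 0.09 at the high dose, and did not pass (adjusted p = 0.589, 0.994, 0.146 and 0.380). The sign of gad2 at the low dose differed under some settings. In that list the vesicular transporter gene slc32a1 stood at -0.35 at the high dose (adjusted p = 0.0822). The gene tspo, which encodes a mitochondrial protein that also binds benzodiazepines, stood at 0.12 ± 0.19 and -0.13 ± 0.19 (adjusted p = 0.966 and 0.80).

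Other lists were called in no comparison. For glutamate receptors and transporters the adjusted p was 0.278 at the low dose, 0.890 at the high dose and 0.388 between the doses, and for the monoamine system it was 0.910, 0.933 and 0.696. For synaptic vesicle and neuronal genes it was 0.845, 0.967 and 0.622, for pituitary markers 0.192, 0.331 and 0.949, and for lens crystallins 0.910, 0.331 and 0.105. For cytosolic ribosomal proteins it was 0.520, 0.249 and 0.342. Skeletal muscle markers had medians of -0.68 at the low dose and -0.93 at the high dose and were not called (adjusted p = 0.0620 and 0.0561), but with slide as a block they were (-1.06 and -1.13, adjusted p = 0.00730 and 0.0171), as were cartilage, bone and skin markers (-0.81 and -0.85, adjusted p = 7.10e-04 and 0.00555). With that block these calls were lost, with adjusted p = 0.811 and 0.815 with an estimated correlation for skeletal muscle, and adjusted p = 0.687 and 0.693 with an estimated correlation for cartilage, bone and skin. With replicate as a block skeletal muscle markers were called at the low dose too (-0.46, adjusted p = 0.0419; adjusted p = 0.928 with an estimated correlation). Without control replicate 3 the skeletal muscle median at the low dose was 0.45 (adjusted p = 0.0450; adjusted p = 0.7499 with an estimated correlation).

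**Figure D3:**
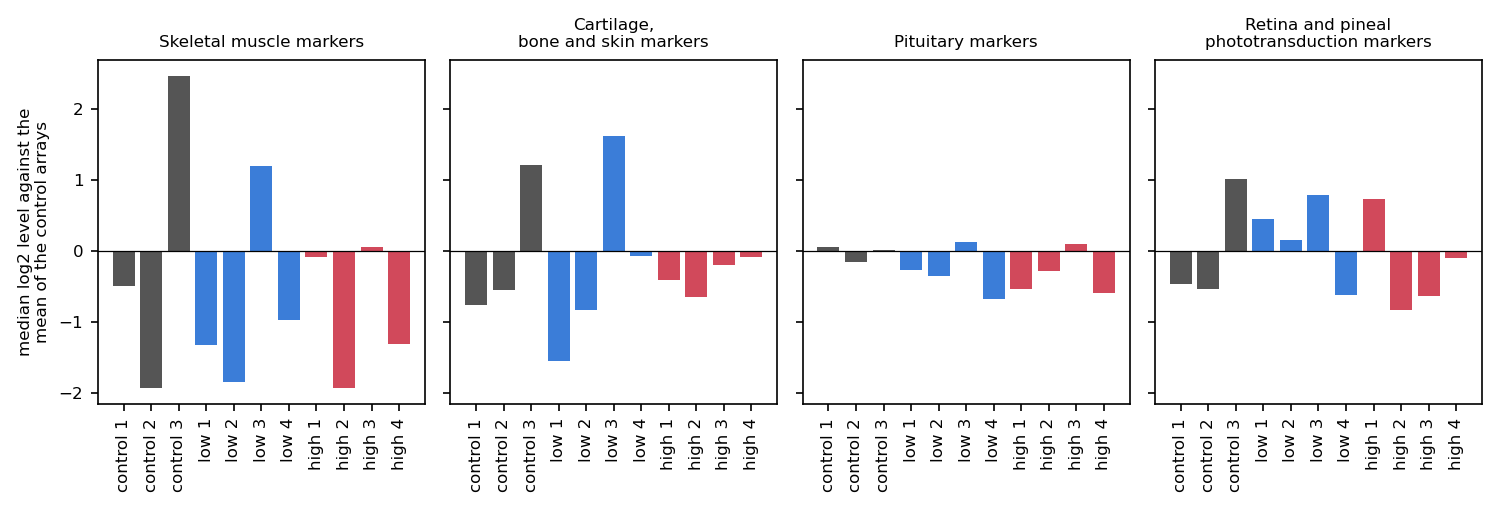
Median change of skeletal muscle, cartilage, bone and skin, pituitary, and retina and pineal markers on each array (vertical axis, log2 signal against the mean of the control arrays), with bars starting at 0 and 1 bar per array in the 3 groups. Skeletal muscle markers stood at 2.47 on control replicate 3 and 1.19 on low-dose replicate 3.

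The third comparison tests the difference between the doses directly. Clock genes made up most of the named changes. At the high dose nr1d4b was higher than at the low dose by 2.08 ± 0.23 (SE, log2 scale, n = 4 and 4, adjusted p = 0.0123), nr1d4a by 1.50 ± 0.14 (0.00291), bmal2 by 1.05 ± 0.08 (0.00194), nr1d1 by 1.01 ± 0.07 (0.00194) and nfil3-2 by 0.92 ± 0.13 (0.0382). In the other direction per3 fell by 1.32 ± 0.12 (adjusted p = 0.00291), bhlhe40 fell by 1.27 ± 0.12 (0.00291), hsp70l fell by 1.07 ± 0.12 (0.0157) and per1b fell by 0.78 ± 0.11 (0.0382), although a second probe of per1b gave -0.85 and did not pass. So nr1d1, which fell at both doses, was less reduced at the high dose. For all 9 of these genes the arrays of the doses did not overlap, which chance gives for 2.86% of genes not chosen by a test, as these were.

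Of the 40 clock genes, 7 rose and 3 fell over all probes, and 13 rose and 7 fell when adjusted over the list alone. Camera called the list as higher at the high dose (median 0.10, adjusted p = 0.00496; adjusted p = 0.368 with an estimated correlation), but not without low-dose replicate 4 (adjusted p = 0.0907) or with replicate as a block (0.0568).

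Camera called 12 of 27 lists between the doses at the preset correlation, 4 up and 8 down, and 0 with an estimated correlation, where 3 had an unadjusted p under 0.05. Neuropeptide genes were lower at the high dose (median -0.30, adjusted p = 7.33e-12; adjusted p = 0.214 with an estimated correlation), with 0 past limma's test over all probes (13 at an unadjusted p under 0.05), and 1 up and 7 down adjusted over the list alone. The somatostatin genes sst1.1 and sst6.1 stood at -0.84 and -0.58 and did not pass (adjusted p = 0.281 and 0.221). Respiratory chain genes were lower (median -0.12, adjusted p = 2.84e-11; adjusted p = 0.368 with an estimated correlation), where ndufv2 stood at -0.30 (adjusted p = 0.32). Heat shock genes were lower (median -0.10, adjusted p = 4.19e-05; adjusted p = 0.214 with an estimated correlation), with 1 down over all probes, hsp70l, and 6 down adjusted over the list alone. Immediate early genes were lower (median -0.14, adjusted p = 0.00112; adjusted p = 0.371 with an estimated correlation), where egr2a and fosab stood at -0.79 and -0.81 and did not pass (adjusted p = 0.466 and 0.638). Genes of xenobiotic metabolism were lower (median -0.12, adjusted p = 0.00411; adjusted p = 0.214 with an estimated correlation), where cyp2ad6 stood at -1.03 (adjusted p = 0.0690) and 1 gene was lower adjusted over the list alone. Neurosteroid genes were lower (median -0.15, adjusted p = 0.0404; adjusted p = 0.368 with an estimated correlation), where hsd17b3 stood at -0.53 (adjusted p = 0.193) and 1 gene was lower adjusted over the list alone. Over all probes 0 members of the respiratory chain, immediate early, xenobiotic and neurosteroid lists passed limma's test, with 15, 14, 12 and 2 at an unadjusted p under 0.05, and in the respiratory chain and immediate early lists 0 passed adjusted over the list alone.

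Among markers of cell types, erythrocyte markers were lower at the high dose than at the low dose (median -0.33, adjusted p = 2.90e-05; adjusted p = 0.371 with an estimated correlation), where the globin gene hbaa2 stood at -1.40 (adjusted p = 0.466). Microglia and leukocyte markers were higher (median 0.18, adjusted p = 2.90e-05; adjusted p = 0.368 with an estimated correlation), where tnfb stood at 0.43 (adjusted p = 0.445). Oligodendrocyte and myelin markers were higher, but at -0.01 under the planned normexp correction (median 0.12, adjusted p = 0.00202; adjusted p = 0.400 with an estimated correlation), and plp1a stood at 0.38 (adjusted p = 0.753). That call was lost without low-dose replicate 1 (adjusted p = 0.0534) or low-dose replicate 3 (0.0541). Cell cycle genes were higher (median 0.09, adjusted p = 2.90e-05; adjusted p = 0.470 with an estimated correlation), where ccnb2 stood at 0.32 (adjusted p = 0.521). Retina and pineal markers were lower, but at 0.15 under the planned normexp correction (median -0.39, adjusted p = 0.0488; adjusted p = 0.910 with an estimated correlation). That call was lost without low-dose replicate 1 (adjusted p = 0.114), low-dose replicate 3 (0.708) or high-dose replicate 2, 3 or 4 (0.536, 0.263 and 0.0999). The neurosteroid call was lost without low-dose replicate 2, 3 or 4 (adjusted p = 0.0695, 0.0860 and 0.148) or high-dose replicate 1 or 2 (0.273 and 0.0840). In the erythrocyte, microglia, oligodendrocyte, cell cycle and retina lists 0 genes passed limma's test over all probes and 0 adjusted over the list alone, with 6, 6, 1, 11 and 3 at an unadjusted p under 0.05.

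Between the doses 23 of 30857 probes passed limma's test, 14 higher and 9 lower at the high dose. Of the 23, 15 belong to a single gene (13 genes) and 12 changed by at least 2-fold. At an unadjusted p under 0.05 there were 1755 probes, where chance gives a share of 0.05 of the 30857. The lenient count was 169 (46 higher, 123 lower) against 308.6 by chance at its p alone. Within slides 1, 2 and 3, 23 of 23 probes kept their direction, again on the arrays that called them, which adds no separate evidence. With slide as a block 15 passed, and per1b (adjusted p = 0.121) and nfil3-2 (0.127) did not. With replicate as a block 32 passed, and per1b (0.0802) did not. The count was 15 without control replicate 2, which enters through the shared spread, 12, 11 or 10 without low-dose replicate 1, 2 or 3, and 10, 14, 11 or 13 without high-dose replicate 1, 2, 3 or 4. The lenient count was 319 without low-dose replicate 4 and 261 without high-dose replicate 2. Without control replicate 3 and low-dose replicate 3 together there were 2, both among the 23.

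Within slides 1, 2 and 3 the list medians between the doses were -0.52, -0.40 and -0.07 for neuropeptides, -0.20, -0.14 and -0.09 for the respiratory chain, -0.14, -0.43 and -0.22 for erythrocytes, and 0.25, 0.15 and 0.06 for the cell cycle. They were 0.45, -0.04 and 0.21 for microglia, -0.17, -0.15 and -0.02 for heat shock genes, -0.30, -0.19 and 0.05 for immediate early genes, and 0.22, 0.16 and 0.04 for oligodendrocytes. They were -0.02, -0.06 and -0.12 for xenobiotic metabolism, 0.02, 0.04 and 0.16 for the clock, -0.11, -0.16 and -0.04 for neurosteroids, and 0.40, -1.25 and 0.14 for the retina. With slide as a block the retina call was lost (adjusted p = 0.642), the other lists were called at the preset correlation (adjusted p-values from 1.26e-19 to 0.00773) but lost, with adjusted p = 0.221 to 0.471 with an estimated correlation and the block, and the p53 list was called as well (0.0275, against 0.0725 without the block; adjusted p = 0.311 with an estimated correlation and the block). With replicate as a block the neurosteroid (0.0682) and retina (0.107) calls were lost.

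The effects of the doses were compared over 30800 probes with a value on every array. Across probes, which are not independent replicates, the log2 changes at the low and the high dose had a Pearson correlation of 0.688 and a covariance of 0.0582. Both share the 3 control arrays, and in simulated data without any change but with those shared controls the correlation was 0.602 at the median and as large as the real one in 392 of 1000 draws. The covariance was as large in 293 of 1000 draws. So the correlation over all probes was within what shared controls alone give. The simulated correlation had an SD of 0.31 over the draws, so this comparison could hardly have told agreement of the doses from none. Of the 87 probes called at the low dose, 27 were called up and 58 down at the high dose too, with 0 in opposite directions. In the simulated data the overlap was 0 at the median, and independent lists would share 0.179 up and 0.681 down. The simulation leaves out real effects and the independent lists leave out the shared controls, so the excess over either is no measure of a shared effect. The 3 control arrays could not be split between the comparisons, so part of the excess may come from the shared controls.

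In a few places a list's median, mean and test differed in sign. At the low dose these were the p53 list (median 0.04, mean -0.10, tested as lower), neuropeptides (median -0.03, tested as higher), lens crystallins (median -0.01, tested as higher) and GABA synthesis (median 0.01, tested as lower). At the high dose they were the p53 list (mean -0.08, tested as higher), synaptic genes (median -0.03, tested as higher) and the proteasome (median near 0, tested as higher). Between the doses they were GABA-A receptor subunits (median 0.04, tested as lower) and the proteasome (median -0.01, tested as higher). None of these list tests passed.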

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

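The tests of the slide and of the time of day for the clock genes, those of other tissue and of diazepam for the skeletal muscle markers, and those for the respiratory chain and heat shock lists were chosen only after the result was seen. Other splits of the samples were counted as planned. The real split called 87 probes between control and low dose, 553 between control and high dose and 23 between the doses, and in each case 1 of 35 splits, the real one, gave as many. The highest of the other splits called 1, 0 and 1 probes. If control and high-dose arrays are unpaired, a random grouping of them is argued against, since the share is 1 of 35. Their correlations by replicate number were 0.0347, 0.311 and 0.201, so whether they are paired was not settled. In every comparison only 7 other splits part as many pairs of replicates as the real one, and the rest part fewer. The highest count of those 7 was 0, but they are too few for a share under 0.05. Under pairing a random grouping is therefore not excluded.

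Clock genes changed at both doses, with 27 of 40 called at one dose or the other. A difference between slides is argued against, since with slide as a block the median size of their changes at the high dose was 1.00 times (1.001) that without, and 25 of 27 stayed called. RNA of other tissue on control replicate 3 and low-dose replicate 3 is argued against too, since without these arrays the median size was 1.00 times (1.002) and 24 of 27 stayed called. The time of day at which brains were taken could move these genes, the share with the same direction at both doses was 1 (27 of 27, which the shared control arrays favour), and dissection times are not given in the sources used here, so time of day and diazepam cannot be told apart for these genes. A response of the clock to diazepam stays open as a hypothesis, as does a shift in the sampling time between the groups. For genes outside the clock list such a shift was not tested and stays open too.

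Skeletal muscle markers were high on control replicate 3 and low-dose replicate 3, where their medians stood at 2.47 and 1.19 (log2 against the mean of the control arrays) and from -1.93 to 0.06 on the 9 other arrays, with -0.08 and 0.06 on high-dose replicates 1 and 3. Array normalization is argued against, since the excess on control replicate 3 under quantile normalization was 1.004 times that under the 75th percentile, and diazepam is argued against, since on that control array the excess over the other controls was 3.71. RNA from other tissue in the dissection was not excluded and stays open, since a share of 0.8286 of the markers (29 of 35) higher on both arrays than on every other array of their group restates the pattern and decides nothing. The abundant muscle gene nme2b.2 stood at 6.41 and 5.79 there against 1.103 to 4.386 on the 9 other arrays, and eno3 at 5.36 and 5.19 against 3.35 to 4.24. The gene mb was more graded, at 5.075 and 4.715 there, 3.956 on control replicate 1, 2.626 on high-dose replicate 1 and -1.328 on low-dose replicate 1. Muscle signal was thus not limited to control replicate 3 and low-dose replicate 3, and leaving them out does not remove all of it. Cartilage, bone and skin markers were high on these arrays as well, at 1.21 and 1.61, while 32 of the 35 muscle markers were well above background on all 9 other arrays too and 0 are in another list.

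Respiratory chain genes had a median of -0.17 at the high dose, a call lost at adjusted p = 0.382 with an estimated correlation. Low detection on high-dose replicate 3 is argued against as the whole cause, since without that array the median was 1.13 times as large, and a slide difference is argued against, since with slide as a block it was 1.40 times as large. An effect of the high dose, a difference in the mix of cells and a shift in the sampling time between the groups all stay open. The lists of cell type markers could speak to the mix only in part. For the heat shock list, whose median was -0.07, the same ratios were 2.02 and 2.11, and a median so near 0 decides nothing.

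Within groups of 4 arrays, 13 of 168 groups tested had 1 array whose gap to the nearest of the others exceeded Dixon's 95% critical value, as a share of the whole range. Chance flags about 1 in 20 groups, or 8.4 here. At the low dose the gap share was 0.891 for gad1b on replicate 2, 0.831 for znf395b, 0.883 for ndrg1b and 0.920 for ndufaf4 on replicate 1, and 0.906 for krt18a.1 on replicate 4. The list medians with such a gap at the low dose were the corticotropic list (0.956, replicate 1) and lens crystallins (0.834, replicate 4). At the high dose the gap share was 0.856 for nfil3 and 0.884 for bhlhe40 on replicate 3, 0.870 for abcc4 on replicate 1, 0.849 for nr1d4b on replicate 4 and 0.940 for nr1d4a on replicate 2. The median of the neurosteroid list had a gap share of 0.890 on replicate 1. The groups spanned from 4.78 to 4.93 for gad1b and from -3.77 to -2.78 for nr1d4b (normalized log2 signal), and from -0.07 to 0.00 for the median of the corticotropic list (log2 change against the mean of the control arrays), so some of these gaps are small in size.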

How the results depend on the processing

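Alternatives chosen only after the result was seen are the repaired normexp correction, keeping marked spots, leaving out control replicate 3 and low-dose replicate 3 together, and the muscle covariate. Scan date could not be tried, since there was 1 date, and the deposited value table changed nothing.
The counts of called probes were 87 at the low dose, 553 at the high dose and 23 between the doses. Lenient counts were 206, 729 and 169, and called list tests were 25 of all and 9 of markers. Calls of named genes were 75, where a gene counts again in each comparison that called it (22, 44 and 9). All these counts held within 1.5 times except as follows. The planned normexp correction gave 24, 98 and 0 called probes and lenient counts of 95, 326 and 56. It gave 46 list tests, 20 marker tests and 32 calls of named genes. Spots of high local background moved it: on high-dose replicate 3, with 259 spots over 100 and a highest background of 57735, the 1st percentile of corrected signal was 830.1 against 55.8 to 117.2 on the others, 174.9 with the highest spot replaced and 59.6 with all replaced. With the correction the median of all probes was 0.211 at the high dose and 0.183 between the doses, against -0.0214 and -0.00648 without. With high backgrounds replaced the called counts were 97, 482 and 20, and the lenient counts 135, 363 and 65. Median centring gave 329 at the high dose and 13 between the doses, and no filter gave 306 and 11 with a lenient count of 346 between the doses. The stricter filter gave a lenient 86 between the doses. Fitting only the 2 groups compared, which leaves fewer samples for the spread, gave 52, 352 and 9. Replicate as a block gave a lenient 340 at the low dose and slide as a block 15 between the doses. Array weights gave 182, 1328 and 35, and a lenient 328 at the low dose. With an estimated correlation 0 list tests and 0 marker tests passed. Without control replicate 3 and low-dose replicate 3 there were 38, 227 and 2 called probes, and 45 calls of named genes. Leaving out 1 array gave 53 to 81, 242 to 594 and 10 to 18 called probes. Lenient counts were then 198 to 266, 602 to 890 and 144 to 319, with 22 to 31 list tests and 6 to 14 marker tests. Calls of named genes were 55 to 71 and the correlation of dose effects was 0.538 to 0.769. Of the 75 calls of named genes, 56, 55 and 56 stood without control replicates 1 to 3. There were 67, 63, 66 and 71 without low-dose replicates 1 to 4 and 58, 58, 69 and 60 without high-dose replicates 1 to 4.
Where a direction reversed, most values were small or not called. Under the planned normexp correction gad2 was -0.017 at the low dose, and at the high dose arr3b was 0.45 and nr1i2 0.25. The tests of some lists turned there, with medians at the high dose of -0.15 for ribosomal proteins, 0.025 for p53, -0.16 for the proteasome and -0.17 for synaptic genes, and between the doses of -0.14 for ribosomal proteins, -0.015 for oligodendrocytes, -0.13 for the proteasome, 0.15 for the retina and -0.087 for synaptic genes. With array weights gad2 was -0.022 at the low dose. Leaving out 1 array gave -0.042 (control replicate 3) to 0.071 (control replicate 1) for gad2 at the low dose, also below 0 without low-dose replicate 1, and -0.051 (low-dose replicate 3) to 0.26 for tspo at the low dose. It gave -1.60 to 0.45 (control replicate 3) for the skeletal muscle median at the low dose, and -0.26 to 0.36 (low-dose replicate 3) for the cartilage median between the doses. Without control replicate 3 and low-dose replicate 3 gad2 was -0.047 at the low dose, and between the doses the cartilage median was 0.36 and the skeletal muscle median 0.46. Apart from the planned normexp correction and the fewer samples of some fits, the cause was not tested. Sign changes of lists that passed in neither setting are not counted here. No called clock gene named in the text reversed. Probes near background limit what could be seen, and the values of arr3b and nr1d4b rest on such signals.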

Other observations

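The tests on sterol synthesis genes, on the clock list without regard to direction and on clock genes called at the low dose were chosen only after the result was seen.

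A few genes of sterol synthesis, the pathway that makes cholesterol, fell at the high dose. The synthase gene hmgcs1 fell by 0.80 ± 0.12 (SE, log2 scale, adjusted p = 0.00944), hmgcra, which encodes the rate-limiting reductase of the pathway, fell by 0.64 ± 0.10 (0.0129), nsdhl fell by 0.70 ± 0.12 (0.0190) and msmo1 fell by 0.93 ± 0.19 (0.0408). These genes were chosen after their values were seen, and so was the list, in which 4 of 23 measured genes fell at the high dose, 0 rose and 0 passed limma's test at the low dose (9 at an unadjusted p under 0.05). The hypothesis that the group as a whole is lower at the high dose may or may not hold. Limma's camera gave an unadjusted p = 0.0175 with an estimated correlation of 0.245 and, without the 4 members seen beforehand, an unadjusted p = 0.0262, but adjusted together with the other lists (28 in all) it did not pass (adjusted p = 0.163 with an estimated correlation). The median was -0.38 over the 23 genes, and 19 of the 19 that were not called lay below 0 (median -0.35). The calls of hmgcra, nsdhl and msmo1 were lost under median centring, with slide as a block and without control replicate 3 and low-dose replicate 3 together. A shift in the sampling time between the groups was not tested for the sterol synthesis genes and stays open.

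Tested without regard to direction, the clock list held more called genes than other genes by Fisher's exact test, with an adjusted p of 1.01e-34 at the high dose, 1.37e-33 at the low dose and 5.47e-23 between the doses. At the high dose this test gave 0.00116 for heat shock genes, 0.0335 for neuropeptides and for xenobiotic metabolism, and 0.0370 for the p53 list. The corticotropic list (0.0525) and the respiratory chain (0.148) did not pass. Fisher's test takes genes as independent, and camera with an estimated correlation called none of these lists. Among the called members, cry5 of the p53 list and per1a of the corticotropic list are clock list genes too. The called members cart2, uts1, nr1i2 and abcc4 did not pass with slide as a block. A planned count of clock genes called at either dose with the larger change at the high dose gave a share of 0.889 (24 of 27), but all 27 had passed at the high dose, so that selection favours the outcome and the count decides nothing. Among the 18 called at the low dose, where the selection favours the opposite, the share was 0.833 (15 of 18).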
